A study of Mus musculus with 3 samples.

How the data were processed

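Total RNA of RN2 cells was extracted with Trizol and sequencing libraries were made with "not so random" primers, which are chosen to avoid ribosomal RNA, per the labels' protocols. The 3 libraries, 1 per hairpin, each came from cells given doxycycline for 4 days. Groups were taken from the sample titles: 1 control hairpin library (shRen.713) and 2 Rnf20 hairpin libraries, replicate 1 with shRnf20.3277 (hairpin 1 in the text) and replicate 2 with shRnf20.3595 (hairpin 2). Nothing in the labels says whether the libraries came from separate cultures or days, so p-values measure only the spread between these libraries, which may be technical, together with the difference between the hairpins.

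The authors deposited FPKM values, fragments scaled to gene length and to the number of mapped fragments, for 21826 loci in each library. Bowtie and Cufflinks, without versions, and genome build mm9 are named in the submitters' processing notes. The file headers carry locus identifiers of the kind Cuffdiff writes. The annotation, the treatment of reads with several matches, strand and any scaling between libraries are not given in the sources used here. No counts, confidence bounds or status flags came with the values. Libraries were joined on the locus identifier, because the order of loci differs between files and 24 gene names had been turned into dates by a spreadsheet. Merged names of several genes stood on 172 rows. The 448 rows that share a name with another row were summed per name, which left 21539 names. Small RNA loci held 95.1%, 96.4% and 96.0% of the FPKM sum in the control, hairpin 1 and hairpin 2 libraries, since FPKM grows very large for short loci. Genes that growing cells use were listed at or near 0 (Gapdh at 0.20, 0.47 and 0 FPKM; Rpl3 at 0.70, 1.25 and 1.76 FPKM in the same order), so an exact 0 can be a failed estimate and is reported only as listed at 0.

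Depth is not stated in the files. A gene with few reads has an FPKM that is a whole multiple of the value of 1 read, so exact ratios between libraries that recur over many loci give the relative depth. The control was 2.39 times as deep as the hairpin 1 library (346 of 11628 loci at that exact ratio, within 0.0003) and 2.53 times as deep as the hairpin 2 library (316 of 11614). Transcript lengths of single-transcript genes then gave 4.56e+06 fragments for the control (258 of 545 solved loci near the mode, quartiles 4.37e+06 and 4.67e+06), 1.90e+06 for hairpin 1 and 1.80e+06 for hairpin 2. Reads per gene were estimated from these totals for transcripts of at least 300 bases, which covered 96.6% of the genes compared, and are approximate. The counting error they give for the median gene is 0.24 on the log2 scale with hairpin 1 and 0.25 with hairpin 2, and it covers counting error only.

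The main scale was log2(FPKM + 1), on which fold changes of low genes are understated, for the 10089 genes with a mean FPKM of at least 1 over the 3 libraries, with values as deposited. A rule of size took genes at least 2-fold lower or higher than the control with both hairpins. The test was limma with a mean-variance trend, Rnf20 hairpins (n = 2) against control (n = 1), two-sided, with Benjamini-Hochberg adjusted p under 0.05; it had 1 residual and 3.58 prior degrees of freedom. No labels pair the libraries, so no block was used. Count tests were not run because no counts were held. The limma SE of a gene with few reads can lie below its counting error, and limma then understates the error. Simulated on 10089 genes of this comparison with 200 changed, the test called 56% of genes changed by 1 and 100% of those changed by 3 on the log2 scale, and 15 of 9889 unchanged genes. The simulated noise was normal, with nearly the same SD for genes of like expression. Real genes of like expression can differ in spread, so these shares need not hold for the real libraries.

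The 28 gene lists, the rules for calls and the rule for named genes were fixed before the data were examined. Each list with at least 5 measured members (21 lists) was placed among 10000 random lists of the same size drawn from 20 bins of mean expression, separately per hairpin; a list outside the 2.5 to 97.5 percentiles on the same side with both hairpins was counted as standing apart. These percentiles describe these libraries and are not p-values. Medians of lists that lie near the median gene change sign with the scaling, so such lists are described by percentile. Limma p-values given as adjusted over a list alone were adjusted within that list, with no correction for the number of lists. The 28 lists were MLL-fusion targets; H2B ubiquitination, PAF1 and H3K79 methylation machinery; stem and progenitor, MYC and ribosome biogenesis, monocyte and macrophage, neutrophil and granule, S phase, G2 and mitosis, p53 target, apoptosis, interferon, NF-kB and inflammatory, immediate early and stress, replication-dependent histone, ribosomal protein, oxidative phosphorylation, glycolysis, ATF4 and unfolded protein response, cholesterol synthesis, small RNA pathway and housekeeping genes; and markers of erythroid, megakaryocyte, B, T and NK, mast, basophil and eosinophil, dendritic and fibroblast cells. Named genes were Rnf20, Rnf40, Hoxa9, Meis1, Myc and Myb, the 12 highest and 12 lowest genes by the smaller of their ratios, and up to 4 members per list. Since most of the 12 highest and lowest were small RNA loci or listed at 0, a further 12 per direction without such loci were added after seeing the data, as were the list members and genes that passed a test and a few members that did not pass (Cdk6, Kit, Dot1l, Lyz2, Msr1, Mpeg1, Zmat3, Fut8, Ctsg, Elane, S100a8 and S100a9).

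Agreement between hairpins was set beside 100 simulated draws of unchanged libraries that share 1 control, with noise taken from the difference between the hairpins in 51 genes of nearest expression. One simulation let the control vary as much as the others, and the other divided its variance by its depth relative to them. Alternatives were pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 5, median and upper-quartile scaling, the highest row per name, folds of 1.5 and 3, limma without trend, an adjusted p under 0.1 and leaving out either hairpin. Leaving out small RNA loci, loci listed at 0, or genes under 50 estimated reads was added after seeing the data, as was subtracting the all-gene medians in the counts of agreement. Positions, lengths and neighbouring genes came from the GENCODE M21 annotation of GRCm38, which is not the build the authors named, and no coordinate was converted. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.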

Results

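RNA sequencing was used to measure gene expression in RN2 cells, a mouse acute myeloid leukemia line on the C57BL/6 background that is driven by the MLL-AF9 fusion oncogene and switches on introduced hairpins in response to doxycycline. The cells expressed a short hairpin RNA for 4 days. The control hairpin, shRen.713, targets Renilla luciferase, which mouse cells lack. Rnf20 hairpin 1 (shRnf20.3277) and Rnf20 hairpin 2 (shRnf20.3595) target different stretches of the mRNA of Rnf20, the ubiquitin ligase that, with Rnf40, attaches ubiquitin to histone H2B. There was 1 library per hairpin, so the control group held 1 library and the Rnf20 hairpin group held 2 libraries that differ in hairpin sequence. The comparison asks which transcripts of MLL-AF9 leukemia cells change in level when Rnf20 is knocked down. Values were the authors' FPKM per gene, and 10089 genes with a mean FPKM of 1 or more were compared on the log2(FPKM + 1) scale. The files give no read counts. From the spacing of low values, depth was estimated at 4.56e+06 fragments in the control library, 1.90e+06 in the hairpin 1 library and 1.80e+06 in the hairpin 2 library. The median gene was backed by an estimated 136.7 reads in the control library, 49.4 in the hairpin 1 library and 45.6 in the hairpin 2 library.

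Rnf20 was lower in both libraries labelled with an Rnf20 hairpin. Its level was 54.9 FPKM in the control, 21.8 FPKM with hairpin 1 and 19.4 FPKM with hairpin 2, which gave log2 ratios to the control of −1.29 and −1.45. The mean log2 ratio was −1.37 (limma SE 0.165, limma adjusted p = 0.22 over all genes). Over the alternative settings the limma adjusted p ranged from 0.041 to 0.54 and was under 0.05 in 1 of them, with the loci listed at 0 in any library left out; without small RNA loci it was 0.060, and without genes under 50 estimated reads 0.058, all 3 settings chosen after seeing the data. Rnf20 lies on chromosome 4 from 49632006 to 49656887 on the plus strand in GRCm38. Its partner Rnf40 had log2 ratios of −0.39 and −0.47, against medians over all genes of −0.18 and −0.19 with hairpins 1 and 2. That shift of the whole distribution applies to every ratio given here, so groups of genes are also described relative to the median gene of the same hairpin. Every ratio also shares the 1 control library, so a difference seen with both hairpins can stem from that library alone.

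**Figure D1:**
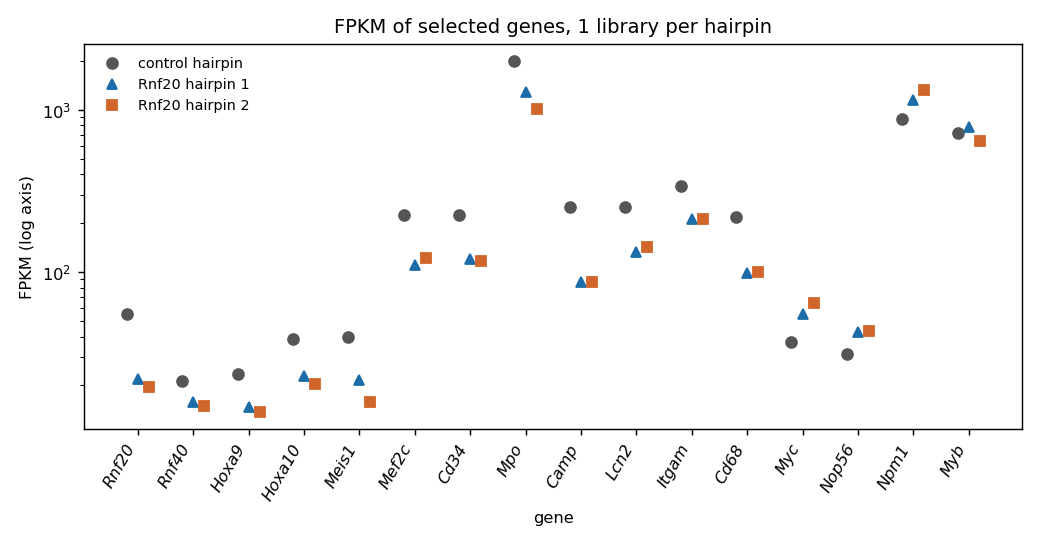
FPKM (log axis) of 16 selected genes in the control library (circles), the hairpin 1 library (triangles) and the hairpin 2 library (squares), 1 library per symbol and no error bars. Rnf20 goes from 54.9 FPKM in the control to 21.8 and 19.4, Meis1 from 39.7 to 21.5 and 15.7, and Myc from 36.9 to 55.4 and 64.1.

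Target genes of the MLL fusion were lower with both hairpins. The homeobox gene Hoxa9 went from 23.4 FPKM in the control to 14.7 and 13.8 FPKM, and its cofactor Meis1 went from 39.7 to 21.5 and 15.7 FPKM. Hoxa10 had log2 ratios of −0.73 and −0.88, the transcription factor gene Mef2c −1.02 and −0.89, and the homeobox gene Pbx3 −0.65 and −0.60. Of the 20 measured members of the list, 14 lay below the median gene with both hairpins and 4 above it, whereas 34.7% of all genes lay below it with both. The list median was −0.36 with hairpin 1 and −0.49 with hairpin 2, at the 0.9 and 0.01 percentiles of 10000 random lists matched on expression. In limma, no member passed an adjusted p of 0.05 over all genes, 4 (Mef2c, Hoxa10, Meis1 and Pbx3, all lower) passed when adjusted over the list alone, and 8 had an unadjusted p under 0.05. Of these 8, the fucosyltransferase gene Fut8 was higher, with log2 ratios of 0.46 and 0.42. After each library was rescaled to a common median, 0 members passed over the list alone, with adjusted p = 0.054 for Mef2c. With a pseudocount of 5, the percentile for hairpin 1 was 4.5. Members without such a difference included Myb, a transcription factor gene of leukemia cell growth, with log2 ratios of 0.11 and −0.17 and a sign that changes with the scaling, and Cdk6, with −0.04 and −0.08, whose mean is above 0 after median rescaling. In GRCm38, Hoxa9 lies on chromosome 6 from 52223100 to 52231089 and Meis1 on chromosome 11 from 18879817 to 19018985, both on the minus strand.

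Among 14 measured stem and progenitor genes, the surface marker Cd34 went from 223.4 FPKM in the control to 120.6 and 116.6 FPKM, with a mean log2 ratio of −0.91 (limma SE 0.129, adjusted p = 0.018 over the list alone and 0.29 over all genes). The ETS factor gene Erg, which did not pass (limma adjusted p = 0.18 over the list alone), had log2 ratios of −0.43 and −0.51, and the receptor gene Kit had 0.20 and −0.08. The list as a whole lay within the range of random lists, at the 86.6 and 47.2 percentiles. The list of H2B ubiquitination, PAF1 and H3K79 methylation machinery, with 24 measured members, was at the 80.5 and 42.0 percentiles. Apart from Rnf20, its members with the lowest mean ratios were the PAF1 complex gene Leo1, at −0.54 and −0.60, and Mll1, at −0.52 and −0.61. The H3K79 methyltransferase gene Dot1l had log2 ratios of −0.07 and 0.03, with a mean above 0 after median rescaling. In limma, Rnf20 was the 1 member of that list to pass when adjusted over the list alone.

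The list of neutrophil and granule genes was lower as a group with both hairpins, but some of its abundant members were not. Camp, which encodes the antimicrobial peptide cathelicidin, went from 250.0 FPKM in the control to 86.2 and 87.2 FPKM, a mean log2 ratio of −1.52 (limma SE 0.128, adjusted p = 0.061 over all genes and 0.0024 over the list alone). Lcn2, which encodes the iron-scavenging granule protein lipocalin 2, had log2 ratios of −0.93 and −0.83, and the myeloperoxidase gene Mpo had −0.62 and −0.97. The list median was −0.44 with hairpin 1 and −0.53 with hairpin 2, at the 0.11 and 0.01 percentiles of matched random lists, and 11 of 18 measured members lay below the median gene with both hairpins while 6 lay above it. Limma called none of the 18 over all genes, with 11 at an unadjusted p under 0.05. Adjusted over the list alone it called 10, of which 8 were lower (Camp, Lcn2, Fcnb, Cebpe, Mpo, Ltf, Ngp and Mmp9) and 2 were higher. The higher pair was Prtn3, which encodes proteinase 3, with log2 ratios of 0.74 and 0.53, and Chi3l3, which encodes a chitinase-like protein, with 1.16 and 1.60. Of the abundant members, Ctsg (1500 FPKM in the control) had log2 ratios of 0.52 and 0.18. Elane (3393 FPKM in the control) had 0.11 and −0.68. The most abundant members were lower with both hairpins, S100a8 (16595 FPKM in the control) at −0.25 and −0.40 and S100a9 (13466 FPKM) at −0.60 and −0.53. Neither passed over the list alone. After median rescaling the calls over the list alone were 2 lower (Camp and Lcn2) and 2 higher (Prtn3 and Chi3l3). With no filter on low values the percentile for hairpin 1 was 6.64. Mmp9 rested on few reads, an estimated 8.42 with each Rnf20 hairpin. Counting errors with hairpins 1 and 2 lay well above the limma SE for Fcnb (0.34 and 0.34 against 0.17) and Ltf (0.30 and 0.30 against 0.16). The same held for Chi3l3 (0.37 and 0.34 against 0.25) and Mmp9 (0.54 and 0.54 against 0.27). For these 4 members limma thus understates the error.

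Several monocyte and macrophage genes were lower with both hairpins. The lysosomal membrane protein gene Cd68 went from 218.1 FPKM in the control to 98.1 and 99.9 FPKM, the NADPH oxidase subunit gene Cybb from 113.2 to 53.6 and 59.2 FPKM, the integrin gene Itgam from 336.2 to 213.2 and 211.5 FPKM, and the transcription factor gene Irf8 from 18.7 to 9.56 and 11.3 FPKM. Cd68, Cybb and Itgam passed limma when adjusted over the list alone, no member passed over all genes, and 6 had an unadjusted p under 0.05, all of them lower. After median rescaling Cd68 and Cybb passed over the list alone, and Itgam did not (limma adjusted p = 0.097). The lysozyme gene Lyz2 had log2 ratios of −0.44 and 0.46 and the scavenger receptor gene Msr1 had 0.25 and 1.08, neither with an unadjusted limma p under 0.05. The median of the 17 measured members was −0.44 with hairpin 1, at the 0.14 percentile of random lists, and 0.18 with hairpin 2, at the 99.98 percentile. With genes of a mean FPKM under 5 left out the list stood apart as lower, at the 0.25 and 0.35 percentiles, as it did without genes under 50 estimated reads, a setting chosen after seeing the data, at 0.02 and 0.18. Its position with hairpin 2 thus depended on which members were included; well-expressed members also had ratios above 0 with that hairpin, such as Lyz2 and Mpeg1 (0.18).

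Genes of ribosome production were higher with both hairpins. Myc itself went from 36.9 FPKM in the control to 55.4 and 64.1 FPKM. Nop56, which encodes a core protein of small nucleolar ribonucleoproteins, had log2 ratios of 0.45 and 0.47, Gnl3, which encodes nucleostemin, 0.46 and 0.43, Npm1, which encodes nucleophosmin, 0.38 and 0.60, and Dkc1, which encodes dyskerin, 0.40 and 0.45. Of the 27 members of the list of MYC and ribosome biogenesis targets, 26 lay above the median gene with both hairpins, and the list median of 0.10 with hairpin 1 and 0.37 with hairpin 2 lay above that of every matched random list. In limma, none of the 27 passed over all genes or when adjusted over the list alone, and 7 had an unadjusted p under 0.05. After median rescaling 6 passed over the list alone, all higher (Myc, Npm1, Nop56, Gnl3, Dkc1 and Tfrc, which encodes the transferrin receptor). Myc lies on chromosome 15 from 61985391 to 61990374 in GRCm38.

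Ribosomal protein genes were higher too, with a list median of 0.38 with hairpin 1 and 0.25 with hairpin 2, above that of every matched random list with both. Of 61 measured members, 47 lay above the median gene with both hairpins. Rpl13 went from 88.4 FPKM in the control to 164.9 and 168.9 FPKM and Rps14 from 5.10 to 19.5 and 25.8 FPKM; limma called both when adjusted over the list alone (adjusted p = 0.038 for each) and called no member over all genes, with 14 at an unadjusted p under 0.05. Rps14 rested on an estimated 13.9 reads in the control, and its counting errors of 0.49 and 0.47 lay above its limma SE of 0.235. After median rescaling 11 members passed over the list alone, all higher. Several ribosomal protein genes were listed far below the level such genes have in growing cells (Rps12 and Rpl36 at 0 in the control), so their single values are uncertain. Reads shared with processed copies of these genes may be a reason, which was not measured. The translation elongation factor gene Eef1a1 had log2 ratios of 0.76 and 0.61. The list of ATF4 and unfolded protein response genes had medians of 0.09 and 0.11, at the 99.9 and 99.95 percentiles, and 13 of its 16 measured members lay above the median gene with both hairpins. Its members with the largest ratios were the serine synthesis gene Psat1, at 0.53 and 0.39, the cystine transporter gene Slc7a11, at 0.47 and 1.01, and, in the other direction, Sdf2l1, at −0.63 and −0.79. Limma called none of the 16 over all genes or when adjusted over the list alone, and 2 had an unadjusted p under 0.05. Oxidative phosphorylation genes, with 51 measured, had medians of 0.01 and −0.06, at the 100 and 97.4 percentiles (medians of 0.20 and 0.14 after median rescaling), with 32 above the median gene with both hairpins. With hairpin 2 the list fell just short of the upper bound, so it did not count as standing apart. It passed with both hairpins after median rescaling (97.76) and upper-quartile scaling (97.75), with no filter (98.42), and, in settings chosen after seeing the data, without small RNA loci (98.77), loci listed at 0 (97.64) or genes under 50 estimated reads (97.70). With hairpin 2 it fell short with pseudocounts of 0.1 (97.485) and 5 (96.465), a mean FPKM of at least 5 (97.08) and the highest row per name (97.295). Limma called none of the 51 over the list alone, and of the 2 with an unadjusted p under 0.05, 1 was higher and 1 lower.

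**Figure D2:**
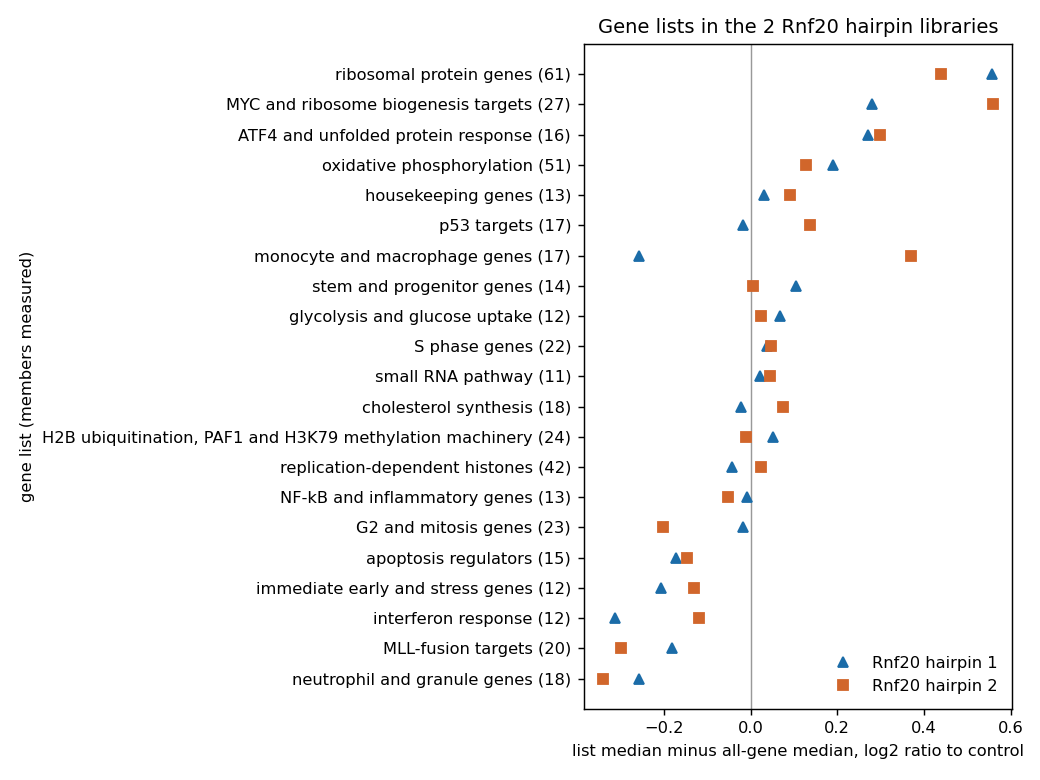
Median log2 ratio to the control of each gene list with at least 5 measured genes, minus the median of all genes for the same hairpin, with hairpin 1 as triangles and hairpin 2 as squares; the number measured stands beside each name and each point is 1 library against the 1 control library. Ribosomal protein genes lie 0.56 and 0.44 above the median gene, MYC and ribosome biogenesis targets 0.28 and 0.56 above it, and MLL-fusion targets and neutrophil and granule genes lie below it with both hairpins.

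Across all genes, 63 were lower and 34 higher by at least 2-fold with both hairpins, so 64.9% of the genes past this rule were lower. After median rescaling the split was 29 lower and 46 higher (38.7% lower), and after upper-quartile scaling it was 28 lower and 46 higher (37.8% lower), so the direction in which more genes lay depends on the scaling. With small RNA loci and loci listed at 0 set aside, the lowest ratios beside those of Rnf20 and Camp included Hpgd, which encodes the enzyme that inactivates prostaglandins, from 159.9 FPKM in the control to 51.8 and 60.1 FPKM, Tmem165, which encodes a Golgi membrane protein, from 751.9 to 317.2 and 274.3 FPKM, Dhrs7, from 115.3 to 47.7 and 50.8 FPKM, the sialic acid receptor gene Siglece, from 39.7 to 14.6 and 16.7 FPKM, Ipcef1, from 25.4 to 9.90 and 9.29 FPKM, and the biliverdin reductase gene Blvrb, from 17.9 to 1.45 and 5.38 FPKM. The highest ratios in the same set included the metallothionein gene Mt2, from 29.0 FPKM to 65.4 and 71.9 FPKM, Rgs1, a regulator of G protein signalling, from 2.32 to 7.27 and 11.7 FPKM, and the granule protein gene Nkg7, from 2.31 to 9.47 and 7.50 FPKM. Few reads backed Blvrb (an estimated 2.40 with hairpin 1 and 8.40 with hairpin 2) and Nkg7 (8.24 in the control). Of the lower genes, 22 were small RNA loci or loci listed at 0 in a library, as were 14 of the higher genes. The 12 lowest of all genes were of this kind, among them Mir15b, Mir1949, Mir1944 and Mirlet7f-1, each listed at 0 in both Rnf20 hairpin libraries. At the short length of these loci and the lower depth of these libraries, an exact 0 does not show that the transcript is absent, and it can also be a failed estimate.

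Limma called 17 genes lower and 3 higher at an adjusted p under 0.05, against 983 lower and 133 higher at an unadjusted p under 0.05. All 20 calls were small RNA loci or loci listed at 0 in a library, and 16 of the 17 lower ones were listed at 0 in both Rnf20 hairpin libraries. The 3 higher ones were Snora78, from 15.5 FPKM in the control to 74.4 and 78.6 FPKM, and Hexb and Gfm2, both listed at 0 in the control, with Hexb at 64.3 and 44.6 FPKM and Gfm2 at 10.1 and 12.7 FPKM in the hairpin 1 and hairpin 2 libraries. With the loci listed at 0 left out, an alternative chosen after seeing the data, limma called 9 genes lower and 6 higher. The 9 were Camp, Hpgd, Tmem165, Cd68, Cd33, Dhrs7, Rpp21, Rnf20 and the merged locus of Inpp5b and Mir698. The 6 were Snora78, Mir715, Rps14, Atg12, Mt2 and Scarna10. Counting errors with hairpins 1 and 2 lay above the limma SE for Rps14 (0.49 and 0.47 against 0.235) and Mt2 (0.27 and 0.27 against 0.164). Atg12, which encodes a ubiquitin-like protein of autophagy, had a mean log2 ratio of 1.20 (limma SE 0.154, adjusted p = 0.037), and Cd33, which encodes a myeloid sialic acid receptor, had −1.17 (limma SE 0.150, adjusted p = 0.037). The test had 1 residual degree of freedom, from the difference between the hairpins, and assumed that the lone control library varies like the others. It was run on values as deposited, where the median gene lies at −0.18 and −0.19, so the lower and higher counts at an unadjusted p include that shift.

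The log2 ratios of the 2 hairpins correlated across genes (Pearson r = 0.52, Spearman rho = 0.51, 10089 genes, which are not independent replicates). Both ratios share the control library. Unchanged libraries simulated with a control as variable as the others gave a mean r of 0.51, and with the variance of the control reduced in proportion to its greater depth they gave 0.29. The highest r of 100 draws was 0.60 and 0.39, respectively. The covariance was 0.154, against simulated means of 0.143 and 0.0572. The 63 genes lower by at least 2-fold with both hairpins stand beside means of 54.3 and 20.1 (33 to 70 and 8 to 29) in the respective simulations and 5.94 for independent lists of 238 and 252 genes. The 34 higher genes stand beside 55.1 and 19.9 (37 to 74 and 9 to 33), and 0.81 for independent lists of 77 and 106. Over all genes and with a control as variable as the others, r and the count of lower genes thus lay within the range of unchanged libraries, and the count of higher genes lay below it. Without small RNA loci and loci listed at 0 (9876 genes), r was 0.54 against simulated means of 0.50 and 0.29, the covariance was 0.0740 against 0.0634 and 0.0259, 41 genes were lower against 20.37 and 2.20 (3.53 for independent lists), and 20 were higher against 20.26 and 1.91 (0.32 for independent lists). Among the 5913 genes with at least 50 estimated reads per library on average, r was 0.67 against simulated means of 0.50 and 0.29, the covariance was 0.0628 against 0.0316 and 0.0128, 20 genes were lower with both hairpins against 1.26 and 0.04 simulated (0.56 for independent lists), and 4 were higher against 1.28 and 0.05 (0.0061 for independent lists). Both of these smaller sets were chosen after seeing the data. In them, with a control as variable as the others, the highest simulated r was 0.527 and 0.530, below the observed values. The counts of lower genes reached at most 38 and 5 in the draws, also below those observed. The counts of higher genes lay within the range of the draws (7 to 31 and 0 to 5). The simulated libraries carry no shift, while the deposited values put the median gene at −0.18 and −0.19, so which of the counts stand out depends on the scaling. After median rescaling the lower and higher genes numbered 29 and 46 of all genes, 10 and 31 in the first smaller set and 6 and 6 in the second. With the 2 all-gene medians subtracted from the ratios, a step added after seeing the data, they numbered 31 and 57, 10 and 42, and 6 and 6. With 1 control library the control could not be split, so where a value lies above the simulated one, part of the difference may still come from the shared control.

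**Figure D3:**
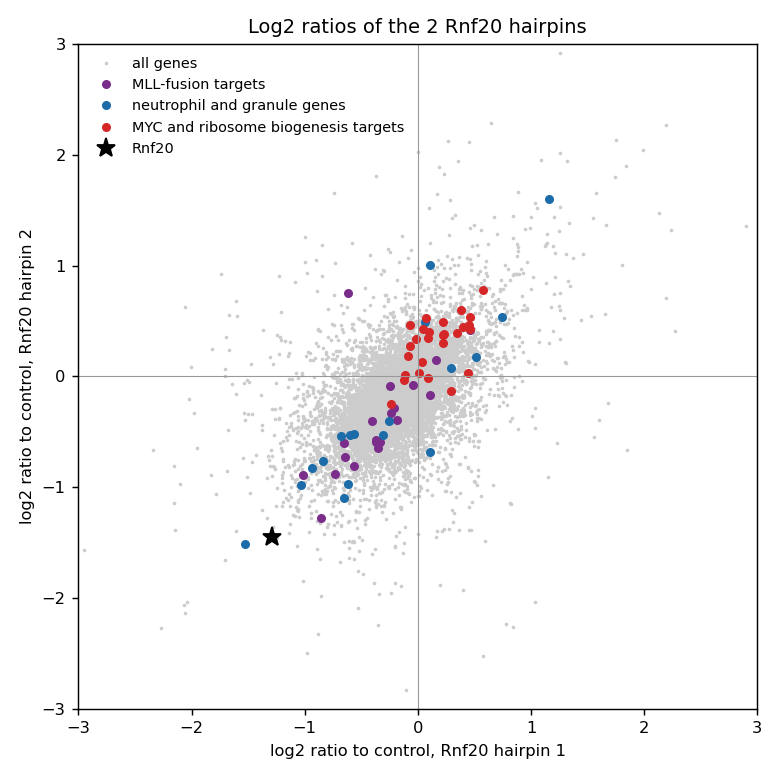
Log2 ratio to the control library with hairpin 1 (x axis) and hairpin 2 (y axis) for 10047 of 10089 genes (grey), with 42 genes beyond 3 on either axis not drawn, MLL-fusion targets in purple, neutrophil and granule genes in blue, MYC and ribosome biogenesis targets in red and Rnf20 as a star. Rnf20 lies at −1.29 and −1.45, and 26 of the 27 MYC and ribosome biogenesis targets lie above the median gene on both axes.

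Markers of other cell types were few. No B cell or dendritic cell marker passed the filter of a mean FPKM of 1, and 2 erythroid, 2 megakaryocyte, 2 T and NK cell, 4 mast cell, basophil and eosinophil and 1 fibroblast marker did. The 4 mast cell and basophil genes all lay above the median gene with both hairpins, for example Mcpt8, a basophil protease gene, at 7.90 FPKM in the control and 9.84 and 13.6 FPKM, and Cpa3, at 4.35, 6.17 and 5.29 FPKM. In limma none of these 4 passed when adjusted over the list alone, and none had an unadjusted p under 0.05. Nkg7, of the T and NK cell list, was the 1 marker of another cell type to pass when adjusted over the list alone with values as deposited (limma adjusted p = 0.0056, and 0.41 over all genes); the other measured member, Cd247, had log2 ratios of −0.39 and −0.44. Tfrc, of the erythroid list, is also in the MYC list and passed over the erythroid list alone after median rescaling (limma adjusted p = 0.021, and 0.0998 as deposited). Alas2, the other erythroid member, had log2 ratios of 0.00 and −0.59. Megakaryocyte members Gp1ba and Itgb3 had 0.23 and 0.17, and −0.02 and −0.02 (above 0 after median rescaling). The fibroblast member, Pdgfrb, had −0.40 and −0.13. Nkg7 rested on few reads, an estimated 8.24 in the control, 14.1 with hairpin 1 and 10.6 with hairpin 2. Its counting error was 0.63 and 0.67 on the log2 scale with hairpins 1 and 2, above its limma SE of 0.259. The limma result for Nkg7 thus understates its error, and its list held only 2 measured members.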

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

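The settings that leave out small RNA loci, loci listed at 0 or genes under 50 estimated reads, or that subtract the all-gene medians, were chosen after seeing the data; the others were planned. No named gene past the rule of size and none of the 5 lists that stood apart as reported changed direction in these settings. The monocyte and macrophage list, not among those 5, stood apart as higher with hairpin 1 left out (99.98 percentile) and as lower with hairpin 2 left out (0.135 percentile). The mean ratios of Myb, Itgb3, Cdk6, Dot1l and Mpeg1, which lie near 0, changed sign under median rescaling. The cause was not tested except where a setting itself removes genes or changes the threshold. Genes lower and higher by the rule of size, 63 and 34 as reported, were 120 and 74 with a pseudocount of 0.1, 32 and 12 with a pseudocount of 5, 460 and 108 at 1.5-fold, 22 and 7 at 3-fold, and 20 and 4 without genes under 50 estimated reads. With no filter 99 were lower, with a mean FPKM of at least 5 there were 17 higher, and median and upper-quartile scaling gave 29 and 28 lower. With 1 hairpin left out at a time the counts ranged from 238 to 252 lower and 77 to 106 higher, since a single ratio then decides, and 7 to 8 lists stood apart in place of 5. Limma, with 17 lower and 3 higher as reported, gave 6 and 1 with a pseudocount of 0.1, 1527 and 66 with no filter (where loci listed at 0 in the Rnf20 hairpin libraries have no spread), 9 and 6 without loci listed at 0, 1 and 1 without genes under 50 estimated reads, 3 lower without small RNA loci and 0 higher without trend. The mean log2 ratio of Rnf20, −1.37, was −1.23 with a pseudocount of 5, −1.17 with median scaling and −1.17 with upper-quartile scaling. The correlation of the hairpins, 0.52, was 0.49 and 0.55 with pseudocounts of 0.1 and 5, 0.56 with a mean FPKM of at least 5, 0.54 without loci listed at 0 and 0.67 without genes under 50 estimated reads. Of single genes, 1059 values moved by less than the spread between hairpins and 377 by more; of list medians, 176 and 75. No paired analysis was possible because the control group holds 1 library and no labels pair it with another. Leaving out a hairpin leaves limma no residual degree of freedom, and the count-based alternative was not run because no counts were held. Depth limits the Rnf20 hairpin libraries most: their median gene rests on under 50 estimated reads.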

Other observations

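Genes of cell division lay low among random lists with hairpin 2. The 23 G2 and mitosis genes had a median log2 ratio of −0.39 with hairpin 2, at the 0.21 percentile of matched random lists, and −0.20 with hairpin 1, at the 44.1 percentile; the difference between hairpins was not tested. Ccna2, the cyclin A2 gene, had −0.48 and −0.77 with hairpins 1 and 2, and the kinesin gene Cenpe had −0.59 and −0.53. The 22 S phase genes lay at the 72.0 and 70.5 percentiles and the 42 histone genes at the 19.3 and 54.5 percentiles. Of the 15 apoptosis regulators, 10 lay below the median gene with both hairpins, among them Bax at −0.56 and −0.70, and the list lay at the 2.65 and 5.49 percentiles. The 12 interferon response genes had medians of −0.49 and −0.31, at the 0.69 and 17.3 percentiles, with 9 below the median gene with both and none above. With no filter on low values the list stood apart, at the 0.70 and 1.43 percentiles. Without loci listed at 0, a setting chosen after seeing the data, it lay within the bounds with both hairpins (3.115 and 22.285). The RNA sensor gene Ifih1 had −0.65 and −0.80. The 12 immediate early and stress genes had medians of −0.39 and −0.32, at the 2.55 and 14.4 percentiles, with Nr4a1 at −1.02 and −0.84. Limma called no member of these 6 lists when adjusted over the list alone; at an unadjusted p under 0.05 there were 7, 1, 7, 4, 1 and 2 in the order given.

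The 17 p53 targets lay at the 40.4 and 90.7 percentiles. Limma called none of them over the list alone, and the 2 with an unadjusted p under 0.05, Bax and Zmat3 (mean log2 ratio −0.90), were both lower. The 13 NF-kB and inflammatory genes lay at the 45.4 and 33.8 percentiles, although the chemokine gene Ccl4 went from 7.47 FPKM in the control to 13.7 and 15.6 FPKM. With values as deposited, limma did not call Ccl4 over all genes or over the list alone. After median rescaling a higher member of the list did pass over the list alone. Lists of 18 cholesterol synthesis genes (43.9 and 83.7), 12 glycolysis genes (76.9 and 55.7), 11 small RNA pathway genes (65.3 and 73.3) and 13 housekeeping genes (53.9 and 69.3) also lay within the range of random lists at the percentiles given for hairpins 1 and 2. Among housekeeping genes, Actb had log2 ratios of −0.33 and −0.31 and B2m −0.37 and −0.35, against −0.18 and −0.19 for the median gene.

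In the weighing that follows, the tests on Hexb and Gfm2 were chosen after their result was seen, and the other tests were written down before the value they measure was seen. The first pattern is the higher level of ribosomal protein genes. If reads shared with copies of these genes were the cause, the shift would sit in members held near 0, but the 14 members with a mean FPKM of at least 100 had a median log2 ratio 0.374 above the median gene (bootstrap SE over genes 0.107), and all 14 lay above it. If too few reads were the cause, it would be missing from well-covered members, but the 16 with at least 100 estimated reads in every library had a median 0.431 above the median gene (SE 0.0928), and all 16 lay above it. Both sets were chosen with the Rnf20 hairpin values included, which favours members that are high there. The SE covers the spread over genes, not between libraries. The counts of 14 and 16 are therefore partly set by the choice, and the tests do not exclude these explanations. The scaling left the direction as it was, with medians of 0.55 and 0.44 after median rescaling. A response of ribosome production to Rnf20 loss and a difference in growth state of the control culture both stay open as hypotheses, since the control is 1 library.

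The second pattern is the pair Hexb and Gfm2, listed at 0 in the control library and at up to 64.3 FPKM in the Rnf20 hairpin libraries; small RNA loci aside, no other gene was at 0 in 1 library and at 10 FPKM or more in both others. The reads expected in the control argue against sampling of few reads, as the smallest number, for Gfm2, was 141.6. Hexb and Gfm2 overlap by 4865 bases on chromosome 13 in GRCm38, so a failed estimate of a shared locus may explain both zeros. Of the 3 annotated genes that overlap in this stretch, 2 were at 0 in the control, Hexb and Gfm2 themselves; the exception, Nsa2, was at 21.2 FPKM but shares only 1 base with Gfm2 in GRCm38 and may not share any in the authors' build, so this explanation could be neither excluded nor shown. The biological explanation, silence of both genes in the control cells alone, was not tested.

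The third pattern is that 1485 loci were listed above 0 in the control only, against 113 listed above 0 in both Rnf20 hairpin libraries and at 0 in the control. If the greater depth of the control were the whole cause, the number should lie near that expected from depth. Among the loci for which this was computed, 1438 were seen where 960 were expected, a ratio of 1.498. More loci were thus seen than were expected from depth alone. The ratio lies between the bounds set beforehand for and against depth, just short of the bound against it (over 1.5). By that rule, depth and a loss of weakly expressed transcripts cannot be told apart by this test. Loci at 0 in the Rnf20 hairpin libraries may thus in part reflect depth. No reads were estimated for the microRNA genes named above, so the part of depth in their zeros is not known.

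A hypothesis of slower elongation through long genes was also tested, because H2B ubiquitination is linked to transcription elongation. It predicts lower ratios for long genes with both hairpins, and a difference of over 0.2 was the bound set for it beforehand. Among 9872 genes with a span in GRCm38, the fifth with the longest span (median 103.8 kb) and the fifth with the shortest (median 4.16 kb) differed in median log2 ratio by −0.079 with hairpin 1 and −0.0347 with hairpin 2. The prediction was not met: in steady-state RNA at this depth, long genes were not lower by the size it named.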
